A study of Homo sapiens with 8 samples.

How the data were processed

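Gene expression was measured in HL-60 cells on NimbleGen arrays with a single colour, Cy3, 1 array for each of vibsanin A, PMA, ATRA and vehicle at 6 h and at 24 h. Per the labels' protocols, cells grew in medium with 10% fetal bovine serum and RNA was cleaned with a NucleoSpin kit. The deposited values were intensities on a linear scale, 1 for each of 45033 rows on each array, which the authors made with RMA, per the submitters' processing notes. Their version, the way rows were summarised and any batch of hybridisation are not given in the sources used here. The arrays had near-identical quantiles, so they had been scaled to each other before deposit. RMA makes the distributions of arrays alike, and a shift of most genes in 1 direction would not be seen. Scanner files were not used here.

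Log2 was taken of each intensity. Rows were named from the platform's probe table: 18188 rows had 1 gene symbol, 0 had several and 26845 were not named here. Older symbols in the gene lists were matched through a table of RefSeq genes, which named no row. The 16583 named genes included 1286 with more than 1 row, for which the mean of the log2 values was taken. A gene was kept if its highest value on the 8 arrays was at or above the median of the table, an intensity of 262, which left 9667 genes. A gene dim in vehicle thus passes only through an agent array where it is bright, which can raise medians of lists and families. Of the 830 kept genes with several rows, 1 (CSF1 under vibsanin A at 6 h) had a row at least 2-fold higher and another at least 2-fold lower in a comparison with an agent, and 3 (CSF1, FCAR and MB) between the vehicle arrays. Probes of near-identical genes may share signal, and values of such genes are uncertain. No background measurement was used, so an intensity of 64 (6 on the log2 scale) was taken as a floor, a limit chosen after seeing the data. Where the dimmer of 2 arrays was under 64, the fold is given as at least the brighter intensity over 64, and no fold is given where both were under it.

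Samples were grouped by the agent and the time in their labels. Differences were taken as log2 of an agent minus log2 of the vehicle array of the same time, and genes at least 2-fold higher or lower were counted. These are values without a test. An effect averaged over both times was tested with limma (lmFit and eBayes) on log2 values, with agent and time as additive terms over all 8 arrays (3 residual degrees of freedom, prior degrees of freedom 1.76), two-sided, with Benjamini-Hochberg adjustment over 9667 genes and a threshold of 0.05. Whether an effect differs between the times could not be tested in this design. Correlations between agents were computed across genes, beside 100 simulations of unchanged groups that share a vehicle array and beside the same value against different vehicle arrays.

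Gene lists were described by the median log2 difference of their measured members and its percentile among 10000 random lists of the same size, matched in 20 bins of mean expression (seed 7). The 26 lists were monocyte and macrophage markers, neutrophil differentiation, promyelocyte and progenitor, retinoic acid response, immediate early and ERK feedback, NF-kB target and cytokine, G2/M and mitosis, DNA replication, ribosome biogenesis, CDK inhibitors and growth arrest, apoptosis regulators, phagocyte NADPH oxidase, adhesion and matrix, protein kinase C and diacylglycerol signalling, heat shock, NRF2 targets, unfolded protein and integrated stress response, interferon response, MHC class II, lysosome, sterol synthesis and uptake, lipid efflux and storage, lymphocyte, erythroid and megakaryocyte, epithelial and stromal, and housekeeping genes. Of 156 medians, 8 moved by over 0.1 when members under 64 were raised to it, and 0 changed sign. Genes named in the text were, for each agent and time, the 10 highest and 10 lowest differences from vehicle, the 5 highest and 5 lowest between vibsanin A and PMA, up to 4 members of a list with the largest differences in the comparison at hand, and always ITGAM, CD14, CSF1R, CD38, CYP26A1, EGR1, MYC, MPO, ELANE, CDKN1A, CYBB and MKI67. Members that limma called in a list, genes moving in opposite directions and the genes with limma values between vibsanin A and ATRA other than CDKN1A and CYP26A1 were named after their values were seen.

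The groups, tests, lists, filter, naming rule and alternatives were fixed before the data were examined, except the floor and 2 alternatives, the floor applied to counts and each row as its own feature, which were chosen after seeing the data. Limma p-values of list members were also adjusted over each list alone. That adjustment was not among the tests fixed beforehand, and it does not account for the number of lists. The alternatives fixed beforehand were quantile normalization, centring each array on its median, no filter and a stricter filter at the 75th percentile (an intensity of 2589), the brightest row of each gene, the mean of both vehicle arrays as control, different vehicle arrays for the agents of a correlation, an intensity trend in eBayes, leaving out each array in turn and a fit of only the 4 arrays of a contrast.

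The limma step was tested on simulated data for vibsanin A against vehicle over 9667 genes. It recovered 19 of 50 genes changed 2-fold at both times, 35 of 50 changed 4-fold, 43 of 50 changed 16-fold and 49 of 50 changed 64-fold, with 2 wrong signs at 2-fold and 11 false calls among 9467 unchanged genes. The list step, tested on simulated data with lists of 20 genes, placed 13 of 200 random lists (6.5%) outside the central 95% and 200 of 200 lists shifted by 1 on the log2 scale. In that simulation differences were shuffled over genes, so members did not move together as genes of a real list may. The 6.5% is therefore not the error rate of the real lists. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 and R 4.3.3 with limma 3.58.1 were used.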

Results

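HL-60 is a human promyelocytic leukaemia line whose cells can mature towards monocytes or towards neutrophils. Total RNA from HL-60 cells was hybridised to 8 single-colour NimbleGen arrays. The cells had been given 10 µM vibsanin A, a diterpenoid found in Viburnum plants, 10 nM phorbol myristate acetate (PMA), a phorbol ester that activates protein kinase C, 1 µM all-trans retinoic acid (ATRA), a ligand of the retinoic acid receptors, or vehicle. Each of these was profiled at 6 h and at 24 h, which gave 8 groups of 1 array each. There were no replicates, so a difference between an agent and vehicle at 1 time is a value without a test. The labels do not say that the arrays came from separate cultures, and p-values then measure only the spread between these arrays, which may be technical. The number of arrays limits the precision of every value.

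The 8 arrays had nearly the same distribution of intensities, with medians between 258 and 269 and 75th percentiles between 2574 and 2601. Between 37.6% and 38.1% of the values on each array lay under an intensity of 64. Of 16583 genes with a name, 9667 were bright enough on at least 1 array to be compared. The 24 h and 6 h vehicle arrays gave the background between arrays without an agent, which holds array noise and culture time together. By the 24 h minus 6 h difference, 33 genes were at least 2-fold higher and 48 were at least 2-fold lower. The standard deviation of that difference across genes was 0.28 on the log2 scale, and it was 0.66 among the dimmest genes and 0.20 among the brightest. The test that the design allows was a limma fit over all 8 arrays of agent plus time, which gives an effect averaged over 6 h and 24 h. In that fit any change of an effect between the times counts as error, the times are not replicates, and a gene that responded at 24 h alone is unlikely to be called.

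**Figure D1:**
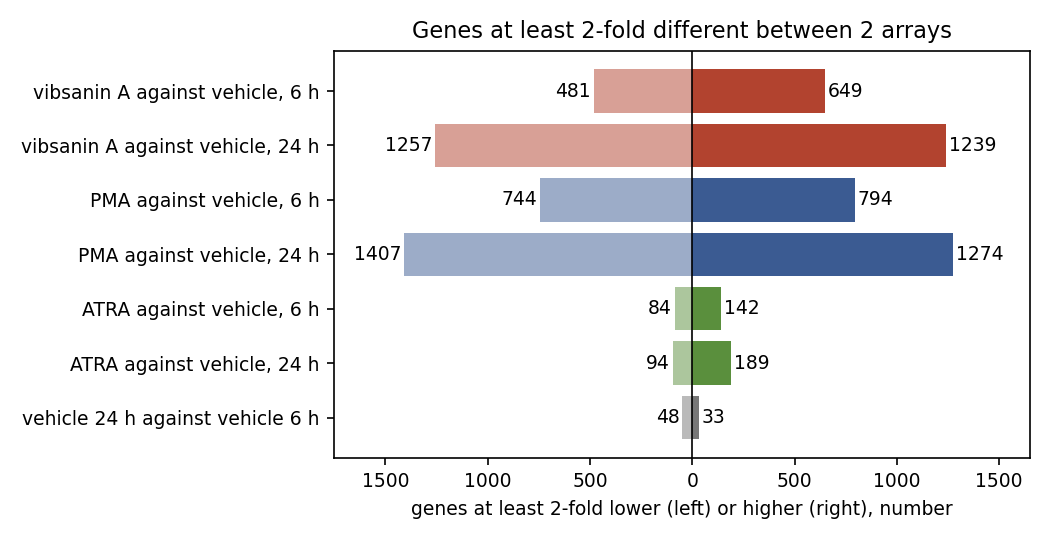
Number of named genes at least 2-fold higher (right, dark bars) or at least 2-fold lower (left, pale bars) on 1 array than on another, of 9667 genes. The bars reach 1239 higher and 1257 lower for vibsanin A at 24 h and 189 higher and 94 lower for ATRA at 24 h, beside 33 and 48 between the vehicle arrays.

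The first comparison asked what vibsanin A did to gene expression in these cells. After 6 h, chemokine, cytokine and immediate early genes were far above vehicle. CCL4, a chemokine that attracts monocytes, was 257-fold higher, with an intensity of 66.3 in vehicle and 17042 with vibsanin A (limma time-averaged log2 difference 7.05, SE 0.75, adjusted p = 0.0226). IER3, an immediate early gene, was 59.8-fold higher (limma adjusted p = 0.0151), and CCL3L1, a near copy of the chemokine gene CCL3 with which it may share probe signal, was 59.3-fold higher. CDKN1A, which encodes the cell cycle inhibitor p21, was 25.5-fold higher at 6 h and 49.2-fold higher at 24 h (limma adjusted p = 0.0151). SELPLG, which encodes the ligand of P-selectin, was 16.6-fold lower at 6 h (limma adjusted p = 0.0147), and MYC, a transcription factor of growing cells, was 8.76-fold lower (limma adjusted p = 0.0536).

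Several other genes with large differences at 6 h were near or below the detection floor in vehicle, so their folds are lower bounds against an intensity of 64, and their order has no meaning. EGR3 was at least 57.8-fold higher, the chemokine gene CCL1 at least 48.4-fold, the amino acid oxidase gene IL4I1 at least 40.9-fold, the myoglobin gene MB at least 25.2-fold, the potassium channel gene KCNJ2 at least 19.1-fold, the gelatinase gene MMP9 at least 16.7-fold and ARHGAP31 at least 8.09-fold. All 7 passed the limma test, with adjusted p from 0.0108 to 0.0377. The 2 rows of MB moved apart between the vehicle arrays, each by at least 2-fold. Among the genes lower at 6 h, the chemokine receptor gene CXCR4 was 11.3-fold lower, HSH2D 10.01-fold, BCL11A 9.37-fold, SOCS2 8.60-fold, the nucleotide receptor gene P2RY2 7.70-fold and CACNA2D3 7.20-fold. TGM5 was at least 6.05-fold lower and ACTL10 at least 6.51-fold. Of these, HSH2D, BCL11A, SOCS2, P2RY2 and TGM5 passed the limma test, and CXCR4 did not (adjusted p = 0.2403).

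At 24 h the differences were larger. GDF15, a secreted factor of the TGF-beta family, was 438-fold higher (intensity 87.1 in vehicle and 38157 with vibsanin A, limma adjusted p = 0.0352). FABP4, a lipid-binding protein of macrophages and fat cells, was at least 546-fold higher, SPOCD1 at least 255-fold, TNFSF15 at least 196-fold, TNFAIP8L3 at least 154-fold, CCL1 at least 153-fold, TDO2 at least 134-fold, MB and SLC12A8 at least 123-fold each and TM4SF19 at least 89.1-fold. HSH2D was 74.8-fold lower, PRTN3, a granule protease of promyelocytes, 64.6-fold lower, and TARP, which lies within a T cell receptor locus and may share probe signal with it, 51.4-fold lower. CACNA2D3 was at least 42.1-fold lower, the DNA glycosylase gene NEIL3 at least 32.6-fold, SOCS2 at least 23.7-fold, CHST4 at least 22.1-fold, the defensin gene DEFA4 at least 19.0-fold, VAT1L at least 18.7-fold and MS4A6A at least 10.6-fold. Of these 24 h genes, the limma test called GDF15, TNFSF15, CCL1, MB, HSH2D and SOCS2. PRTN3 had an adjusted p of 0.342, with log2 differences of −0.91 at 6 h and −6.01 at 24 h.

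Genes of the early response to mitogens and of NF-kB signalling were higher at both times. Of 31 measured immediate early and ERK feedback genes, 25 were at least 2-fold higher at 6 h and 24 were at 24 h, with 0 and 3 at least 2-fold lower. Their median log2 difference was 1.76 at 6 h and 2.20 at 24 h (2.10 with dim intensities raised to 64), above all 10000 random lists matched on expression. PHLDA1 was higher by 4.26 and 7.42 on the log2 scale, and EGR1, a zinc finger factor of the early response, by 3.19 and 2.20 (limma adjusted p = 0.0352). By limma, 17 of the 31 rose and 0 fell, and 27 rose when adjusted over the list alone. Of 26 NF-kB target and cytokine genes, 22 were at least 2-fold higher at 6 h and 20 at 24 h, with medians of 2.69 and 2.93. CCL3, a chemokine, was higher by 5.48 at 6 h, and IL1B, the gene of an inflammatory cytokine, by 5.74 at 24 h. IL1A was at least 18.7-fold higher at 6 h and at least 81.2-fold higher at 24 h. By limma, 17 rose and 0 fell over all genes, against 21 and 1 adjusted over the list alone.

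Markers of monocytes and macrophages were mostly higher at 24 h, and granule and progenitor genes were lower. Of 27 named monocyte and macrophage markers 17 passed the filter on dim genes. A marker dim in vehicle passes only through an agent array where it is bright, which can raise the median. Of the 17, 6 were at least 2-fold higher and 2 lower at 6 h, against 11 higher and 4 lower at 24 h. The median was 0.43 at 6 h, which became 0.06 with dim intensities raised to 64, and 2.16 at 24 h. SPP1, the gene of osteopontin, was higher by 8.18 at 24 h, the scavenger receptor gene CD36 by 6.25 and ITGAM, which encodes the integrin CD11b, by 5.17 (36.0-fold, limma adjusted p = 0.0818). By limma 1 marker rose (MMP9) and 1 fell (IRF8, −1.40 and −2.45), against 6 and 1 adjusted over the list alone. CD14, a receptor for lipopolysaccharide on monocytes, was 3.21-fold lower at 6 h and 19.1-fold higher at 24 h. Of 15 promyelocyte and progenitor genes, 3 were at least 2-fold lower at 6 h and 13 at 24 h, 0 were higher at either time, and the median was −0.72 and −2.99. Their limma count was 0 over all genes and 0 adjusted over the list alone. The log2 difference at 24 h was −5.39 for MS4A3 and −4.35 and −4.18 for the granule protein genes AZU1 and CTSG. MPO, the gene of myeloperoxidase, had intensities of 15994 in vehicle and 18978 with vibsanin A at 6 h, and of 19144 and 4518 at 24 h, and the elastase gene ELANE had 21119 and 15649 at 6 h and 18347 and 1370.5 at 24 h.

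Neutrophil genes moved both ways. Of 26 named, 11 passed the filter. Of these, 0 were at least 2-fold higher and 3 lower at 6 h, against 3 higher and 5 lower at 24 h, with medians of −0.54 and −0.75. S100A8 was lower by 2.23 at 6 h and at least 5.96-fold lower at 24 h, and BPI, the gene of a bactericidal granule protein, was at least 11.5-fold higher at 24 h. By limma 1 neutrophil gene rose (ITGB2, an integrin that monocytes also carry) and 0 fell, against 1 and 3 adjusted over the list alone. The 6 measured genes of the phagocyte NADPH oxidase had medians of 0.23 and 0.52, and 1 (NCF1) rose by limma over all genes and adjusted over the list alone. Adhesion and matrix genes were higher, 12 of 25 at 6 h and 17 at 24 h by at least 2-fold, with 2 and 4 lower and medians of 0.98 (0.77 with dim intensities raised to 64) and 2.12. ICAM1 was 31.9-fold higher at 6 h (limma adjusted p = 0.0108), and the intermediate filament gene VIM was higher by 5.30 and the integrin gene ITGB7 by 5.14 on the log2 scale at 24 h. By limma 6 rose and 1 fell (SELPLG), against 13 and 2 adjusted over the list alone.

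Cell cycle genes were near vehicle at 6 h and lower at 24 h. All 28 measured DNA replication genes were at least 2-fold lower at 24 h and 0 were at 6 h, with medians of −2.26 and −0.23. GINS1 was at least 5.23-fold lower at 24 h, and MCM10, the licensing factor gene CDC6 and GINS2 had log2 differences of −3.66, −3.21 and −3.16. Of 26 genes of G2/M and mitosis, 23 were at least 2-fold lower at 24 h and 0 were at 6 h, with medians of −2.05 and 0.15. KIF20A, a kinesin of dividing cells, was at −2.99, the cyclin gene CCNA2 at −2.74 and the kinase gene AURKB at −2.73. Intensities of MKI67, a proliferation marker, were 1058 in vehicle and 1606 with vibsanin A at 6 h and 702 and 129.2 at 24 h. For both lists limma called 0 genes over all genes and 0 adjusted over the list alone, and a difference at 24 h alone counts against itself in that test. Of 14 CDK inhibitor and growth arrest genes, 4 were at least 2-fold higher and 2 lower at 6 h, against 3 and 4 at 24 h. By limma 4 rose, CDKN1A, CDKN2B, RB1 and MXD1, and 0 fell, against 6 and 2 adjusted over the list alone. The 24 measured ribosome biogenesis genes had medians of −0.68 and −0.43, both below at least 99.8% of random lists, and POLR1B was lower by 1.22 at 6 h. By limma 0 changed over all genes and 12 fell adjusted over the list alone.

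Among the stress and metabolic lists, some sterol and oxidative stress genes were higher. Of 14 sterol synthesis and uptake genes, 5 were at least 2-fold higher at each time, with medians of 0.79 and 0.63 beside 0.25 between the vehicle arrays, and STARD4, INSIG1, SQLE and MSMO1 rose by limma (4 over all genes, 8 adjusted over the list alone). STARD4 was higher by 2.75 and 3.78. Of 16 NRF2 target genes, 5 were at least 2-fold higher at each time and 11 were within 2-fold of vehicle, with medians of 0.33 and 0.31, and HMOX1, the gene of a haem-degrading enzyme, was higher by 3.21 and 4.97. Between the vehicle arrays its difference was −2.78. By limma 3 NRF2 targets rose over all genes and 3 adjusted over the list alone. Lysosome genes had medians of 0.04 at 6 h and 0.76 at 24 h, where 9 of 23 were at least 2-fold higher, CTSH and CTSL by 3.16 each, and limma called 2 higher over all genes and 4 adjusted over the list alone. Of 26 named interferon response genes 16 passed the filter, with medians of 0.21 and 1.24. GBP2 was at 2.48 and HERC5 at −2.40 at 24 h. By limma 3 were called higher and 1 lower, against 4 and 1 adjusted over the list alone.

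Apoptosis regulators included 5 of 18 that were at least 2-fold higher and 3 lower at 24 h. The survival gene BCL2 had differences of −1.55 and −3.04 and CFLAR, a caspase inhibitor, of 1.93 and 2.09. By limma 4 rose and 1 fell, against 6 and 1 adjusted over the list alone. Protein kinase C and diacylglycerol signalling genes had medians of −0.11 and 0.11. PRKCZ, at −1.91 and −2.66, was the 1 member to fall by limma, against 1 that rose and 2 that fell adjusted over the list alone. RASGRP3 was higher by 3.05 at 24 h. Heat shock genes had medians of 0.08 and −0.20, and 1 member, BAG3, rose by limma over all genes and adjusted over the list alone. Genes of the unfolded protein and integrated stress responses had medians of −0.14 and −0.32, with PPP1R15A at 1.78 and 2.64 and the serine synthesis gene PSAT1 at −3.90 at 24 h. By limma 1 of these 24 rose and 1 fell, over all genes and adjusted over the list alone. Lipid efflux and storage genes had medians of −0.18 and 0.26, PPARG was higher by 5.95 at 24 h, and 0 rose and 1 fell (MYLIP) by limma under both adjustments. Of 11 named MHC class II genes 6 passed the filter, and 3 of these were at least 2-fold lower at 24 h, with HLA-DRA at −2.88. Limma called 0 of them under both adjustments.

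Markers of other cell types were little measured. Of 14 named lymphocyte markers 2 passed the filter. IL7R was higher by 4.21 and 5.18 (limma adjusted p = 0.0187) and NKG7 was at −0.15 and −0.59, and 1 rose by limma under both adjustments. Of 15 named erythroid and megakaryocyte markers 3 passed, with medians of −1.12 and −1.39, and KLF1 and EPOR fell by limma under both adjustments. Of 17 epithelial and stromal markers 2 passed, KRT8 and KRT18, with medians of 0.28 and 0.36, and limma called 0 over all genes and 1 higher adjusted over the list alone. The 12 housekeeping genes had medians of 0.01 and 0.02 and limma called 0 under both adjustments.

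Over all genes, vibsanin A gave 649 that were at least 2-fold higher and 481 lower at 6 h, and 1239 higher and 1257 lower at 24 h. At both times 528 were higher and 264 lower, where 83.2 and 62.5 would be shared by independent lists of those sizes, and these comparisons use different vehicle arrays. By limma 458 genes rose and 272 fell averaged over the times at an adjusted p under 0.05, and 2843 had an unadjusted p under 0.05. All 730 called had the same sign at both times, which the fit favours because a change between the times counts as error. Every array left out changed that count of 730: it became 33 without the vibsanin A 6 h array, 102 without either PMA array, 21 without either ATRA array, and 0 without the vibsanin A 24 h array or without the 6 h or 24 h vehicle array (1343, 2247 and 1694 at an unadjusted p under 0.05). It was also 0, with 1613 unadjusted, when the spread came from the 4 vibsanin A and vehicle arrays alone.

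**Figure D2:**
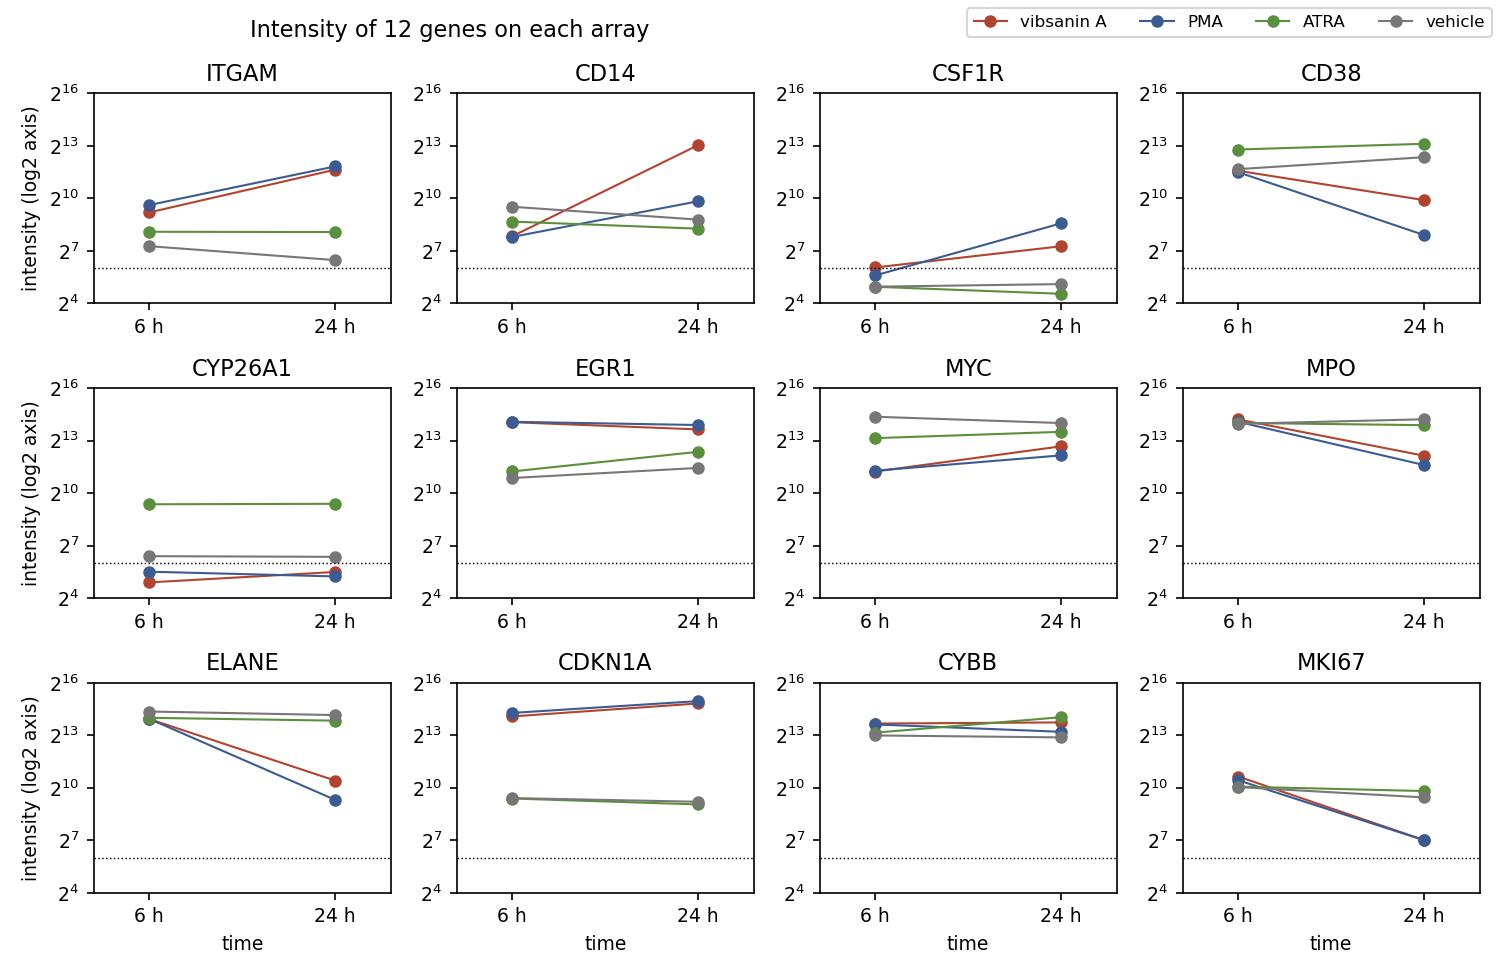
Intensity, on a log2 axis, of 12 genes chosen before the data were examined, with 1 array per point, colours for the agents and a dotted line at an intensity of 64. ITGAM reached 3203 with vibsanin A and 3642 with PMA at 24 h, while CYP26A1 was above vehicle with ATRA and not with vibsanin A or PMA.

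The second comparison gave the response to PMA, a known inducer of macrophage-like maturation in this line. After 6 h, CCL4 was 464-fold higher than in vehicle, the largest 6 h difference from vehicle among genes above the floor on both arrays (limma adjusted p = 0.0151). HSH2D was 35.5-fold lower at 6 h (limma adjusted p = 0.0234), CXCR4 24.6-fold lower and SOCS2 17.9-fold lower. At 24 h GDF15 was 486-fold higher (limma adjusted p = 0.0221), the progenitor transcription factor gene MYB 135-fold lower (limma adjusted p = 0.0847) and MS4A3 74.8-fold lower. CDKN1A was 29.2-fold higher at 6 h and 54.0-fold higher at 24 h (limma adjusted p = 0.0109), and MYC had log2 differences of −3.08 and −1.85 (limma adjusted p = 0.0357).

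Other genes with large differences under PMA were close to the floor on 1 of the arrays. At 6 h CCL1 was at least 111-fold higher, EGR3 at least 75.1-fold, MB at least 66.2-fold, KCNJ2 at least 56.5-fold, IL4I1 at least 49.8-fold (limma adjusted p = 0.00524), the cytokine genes IL1A and LIF at least 45.1-fold and 44.4-fold, CCL7 at least 30.1-fold and MMP9 at least 20.1-fold. SELPLG was at least 25.4-fold lower, CABLES1 at least 15.8-fold, BCL11A at least 9.67-fold, PLD6 at least 7.64-fold, EXPH5 at least 4.91-fold, the syndecan gene SDC1 at least 4.17-fold and NRXN2 at least 3.85-fold. At 24 h FABP4 was at least 548-fold higher, SPOCD1 at least 357-fold, MB at least 296-fold, TDO2 at least 195-fold, TM4SF19 at least 170-fold, SLC12A8 at least 156-fold, INHBA, a TGF-beta family gene, at least 151-fold, CCL1 at least 112-fold and MLPH at least 111-fold. PRTN3 was at least 362-fold lower at 24 h, TARP at least 195-fold, ANKRD22 at least 120-fold, HSH2D at least 100-fold, CACNA2D3 at least 42.1-fold, SOCS2 at least 23.7-fold, and PLPPR3 and VAT1L at least 18.7-fold each.

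Signalling lists were above vehicle under PMA too. Of the 31 immediate early and ERK feedback genes, 25 were at least 2-fold higher at 6 h and 24 at 24 h, with medians of 2.08 and 2.47, and 22 rose and 0 fell by limma, against 25 and 1 adjusted over the list alone. Of the 26 NF-kB target and cytokine genes, 22 were at least 2-fold higher at 6 h and 19 at 24 h, with medians of 2.84 and 2.69 (2.40 at 24 h with dim intensities raised to 64), and 17 rose and 0 fell, against 21 and 1 adjusted over the list alone. Monocyte and macrophage markers had a median of 0.52 at 6 h, which was 0 with dim intensities raised to 64 and −0.038 with no filter on dim genes, and of 2.18 at 24 h with 11 of 17 at least 2-fold higher and 4 lower. By limma 2 of these markers rose (ITGAX and MMP9) and 1 fell (IRF8), against 6 and 1 adjusted over the list alone. At 24 h SPP1 was higher by 8.10, CD36 by 5.77 and ITGAM by 5.36 (limma adjusted p = 0.0608), and CSF1R, the receptor for the macrophage growth factor, was at least 5.96-fold higher. CSF1R intensities at 24 h were 34.4 in vehicle, 382 with PMA and 154 with vibsanin A.

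Of the promyelocyte and progenitor genes, 12 of 15 were at least 2-fold lower with PMA at 24 h, with a median of −3.24, AZU1 at −5.54 and ELANE at −4.85, and 1 (MYC) fell by limma under both adjustments. All 28 DNA replication genes were at least 2-fold lower at 24 h and 0 at 6 h, with medians of −2.07 and −0.23, and 20 of 26 G2/M and mitosis genes were, with medians of −1.84 at 24 h and 0.26 at 6 h. Limma called 0 in either list under both adjustments. Ribosome biogenesis genes had medians of −0.80 and −0.50, and 5 of 24 fell by limma, against 15 adjusted over the list alone. Adhesion and matrix genes had medians of 1.16 (1.03 with dim intensities raised to 64) and 2.16, with 9 higher and 2 lower by limma, against 13 and 3 adjusted over the list alone. Neutrophil genes had medians of −0.78 and −1.39, with CXCR2 at −2.16 and −3.47, and 1 rose and 3 fell by limma, against 2 and 5 adjusted over the list alone. Sterol genes had medians of 0.79 and 1.02, and 7 of 14 rose by limma under both adjustments.

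Medians of the remaining lists under PMA, at 6 h and 24 h, were 0.48 and 0.13 for CDK inhibitors, 0.52 and 0.41 for apoptosis regulators, 0.35 and 0.15 for the NADPH oxidase, 0.02 and −0.05 for protein kinase C signalling, 0.01 and −0.25 for heat shock genes and 0.38 and 0.18 for NRF2 targets. For the unfolded protein response they were −0.24 and −0.46, for interferon response genes 0.06 and 0.97, for MHC class II genes 0.05 and −1.31, for lysosome genes 0.02 and 0.78, for lipid efflux genes −0.06 and 0.21 and for retinoic acid response genes −0.18 and −0.21, the last of which was −0.034 with dim intensities raised to 64. IL7R was higher by 4.91 and 4.70 among the 2 lymphocyte markers, the 3 erythroid and megakaryocyte markers had medians of −1.41 and −1.83, and KRT8 and KRT18 had medians of 0.24 and −0.03. Housekeeping genes had medians of 0.00 and −0.05.

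PMA gave 794 genes at least 2-fold higher and 744 lower at 6 h, and 1274 higher and 1407 lower at 24 h. At both times 594 were higher and 413 lower, where independent lists would share 105 and 108. By limma 671 rose and 571 fell, and 3253 had an unadjusted p under 0.05. All 1242 called had the same sign at both times, which the fit favours here too. Their number became 498 without either vibsanin A array, 356 without either ATRA array, 3 without either PMA array, and 0 without the 6 h or the 24 h vehicle array (2578 and 1964 unadjusted) or with the 4 PMA and vehicle arrays alone (1748 unadjusted).

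**Figure D3:**
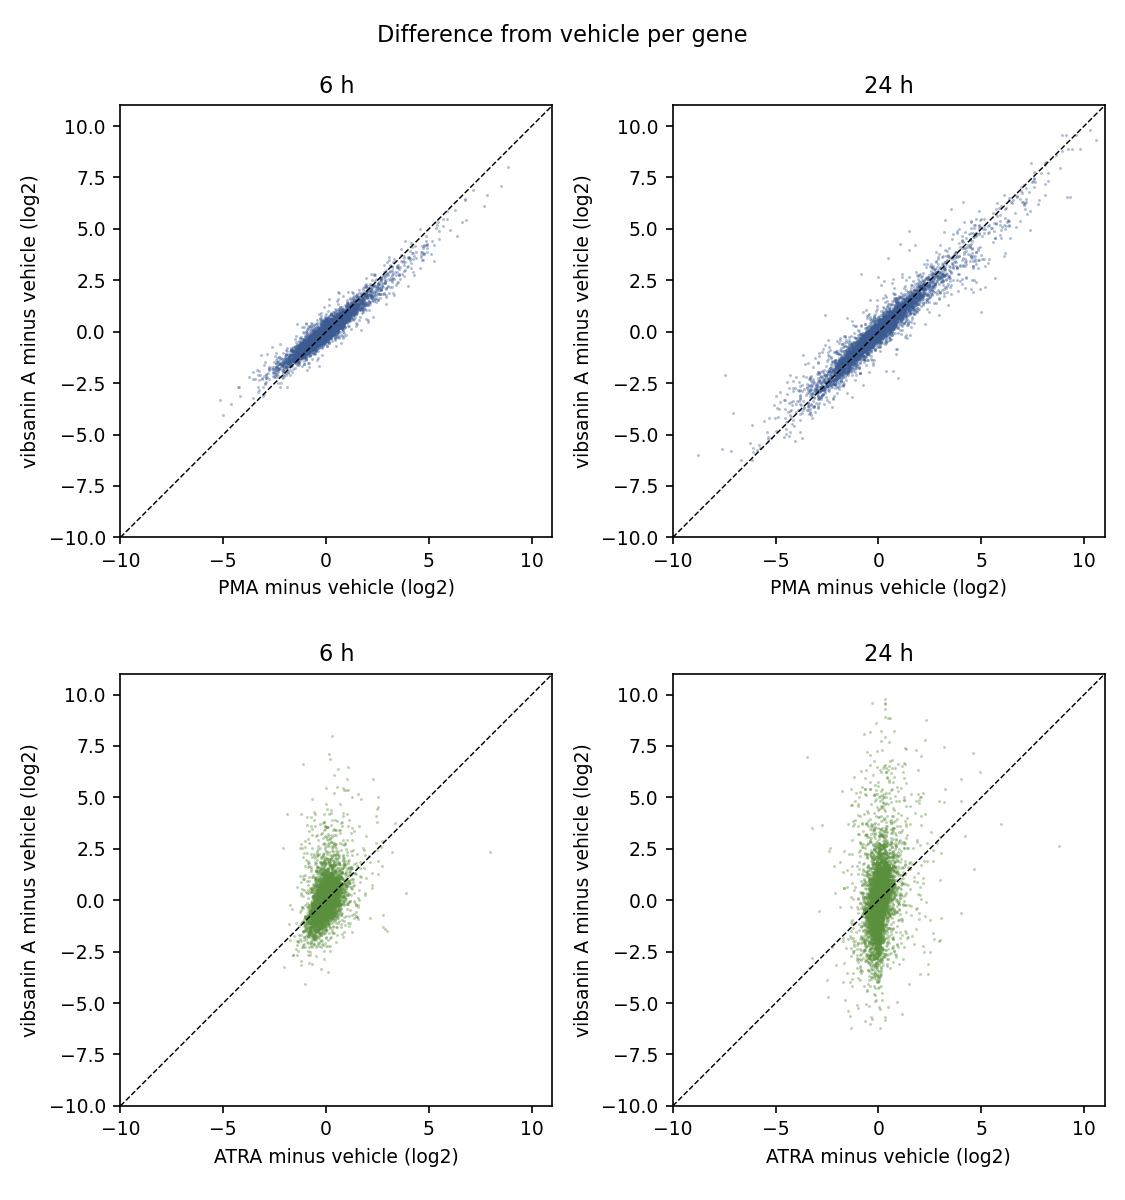
Log2 difference from vehicle of each of 9667 genes, with vibsanin A on the vertical axis against PMA (upper panels) or ATRA (lower panels) on the horizontal axis, at 6 h and 24 h, and a dashed line of equal differences. Points lie along the line for PMA (r = 0.956 and 0.965) and spread vertically for ATRA (r = 0.414 and 0.281).

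The third comparison set vibsanin A at 10 µM beside PMA at 10 nM, so the doses differ and are not matched. Of the genes at least 2-fold higher at 6 h, 607 were so under both agents, and of those lower, 436, while at 24 h the shared numbers were 1100 and 1137. No gene was at least 2-fold higher under 1 agent and lower under the other (0 at each time). CD14, ANKRD22 and CXCR4 were among those that differed most between the agents. At 24 h CD14 was 9.23-fold higher with vibsanin A than with PMA (intensities of 8457 and 916), and ANKRD22, 7707 in vehicle, was at 1786 with vibsanin A and 43.7 with PMA, at least 27.9-fold apart. CXCR4 was at 2061 with vibsanin A and 18917 with PMA at 24 h, 9.18-fold lower.

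Other genes lower with vibsanin A than with PMA at 24 h were the zinc transporter gene SLC30A3 (16.4-fold), TEX9 (8.23-fold), TGM3 (8.12-fold) and TRIM54 (7.10-fold), while the receptor genes HCAR2, FFAR2 and PTAFR were at least 5.87-fold, 5.23-fold and 4.27-fold higher. At 6 h HSH2D was 3.55-fold higher with vibsanin A than with PMA, FOXK1 3.52-fold and FUT7, a fucosyltransferase gene, 3.37-fold, and RAB37 and WNT7B were at least 2.40-fold and 1.95-fold higher. XIRP1 was 3.57-fold lower at 6 h, the nuclear receptor gene NR4A3 3.40-fold, LIF 3.22-fold and FMN2 at least 1.04-fold, and KRT79 was under the floor on both arrays. MYB and PRTN3, lower than vehicle under both agents at 24 h, were lower under PMA than under vibsanin A, MYB at −7.08 and −3.97, and PRTN3 at least 362-fold and 64.6-fold lower.

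Several gene lists differed between the agents, with 1 array each, by medians beyond nearly all of the 10000 random lists, though by less than 2-fold. At 24 h the vibsanin A minus PMA median was 0.52 for promyelocyte and progenitor genes (percentile 100), 0.25 for NADPH oxidase genes (percentile 100) and for retinoic acid response genes (99.98), 0.23 for neutrophil genes (99.7) and 0.12 for NRF2 targets (99.4). With dim intensities raised to 64 the neutrophil median was 0 and the retinoic acid median 0.03, so these 2 rested on dim genes. It was −0.27 for sterol genes, −0.21 for DNA replication genes and −0.16 for G2/M and mitosis genes, each below all random lists. Immediate early genes were at −0.24 at 6 h and −0.19 at 24 h, below all random lists at both times. NF-kB targets went from −0.18 at 6 h (percentile 0.02) to 0.18 at 24 h (99.99), and MHC class II genes from −0.24 (1.59) to 0.30 (97.9). At 6 h adhesion genes were at −0.18 (0.04) and ribosome biogenesis genes at 0.10 (99.8), beside 0.02 and 0.06 at 24 h. For promyelocyte genes at 6 h the median was −0.01. The other lists with at least 5 measured members lay between percentiles 4.53 and 96.5 at both times. Between the vehicle arrays, which had no agent, some medians reached such percentiles too. They were −0.22 for NF-kB targets (0.13), −0.30 for MHC class II genes (1.8), 0.25 for sterol genes (99.98) and −0.20 for NRF2 targets (0.28). For the other lists named here the vehicle percentiles lay between 4.185 and 78.57. An extreme percentile thus does not by itself show a difference between the agents.

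Across genes, the differences from vehicle of the agents correlated with r = 0.956 at 6 h and 0.965 at 24 h (Spearman's rho 0.918 and 0.952), 1 of 3 pairs of agents computed at each time, and genes are not independent replicates. Both comparisons share a vehicle array, which alone gives r = 0.501 in simulations of unchanged groups. The covariances were 0.68 and 1.87 beside a simulated 0.04. With the agents set against different vehicle arrays, r was 0.910 and 0.900 at 6 h and 0.942 and 0.943 at 24 h. Independent lists would have shared 53.3 higher and 37.0 lower genes at 6 h and 163 and 183 at 24 h, and part of the excess may come from the shared vehicle array. Limma called 437 of the same genes higher under both agents and 263 lower, where independent lists would share 31.8 and 16.1, and 0 in opposite directions. Both contrasts share the vehicle arrays and each gene's estimate of spread, so part of this excess too may come from that.

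Differences from vehicle were smaller under vibsanin A at 6 h. Of 1301 genes with a mean difference of both agents of at least 2-fold at 6 h, 1064 (81.8%) had the smaller difference under vibsanin A, and the median ratio of the differences was 0.832 (quartiles 0.722 and 0.952). At 24 h the share was 59.6% of 2567 genes and the median ratio 0.955 (quartiles 0.819 and 1.09). Between the agents directly, 57 genes were at least 2-fold higher and 49 lower with vibsanin A at 6 h, and 140 and 128 at 24 h. The standard deviations of these differences were 0.29 and 0.38, beside 0.28 between the vehicle arrays, which also differ in culture time. Limma called 0 genes between the agents averaged over the times, with 141 at an unadjusted p under 0.05 and a smallest adjusted p of 0.9999. The 95% interval of the difference reached a median of 0.51 to either side, and for 7115 genes (73.6%) it lay within a 2-fold difference either way, so for the others larger differences were not excluded. For CD14 the interval ran from −2.41 to 5.66 and for CDKN1A from −1.05 to 0.72.

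The fourth comparison gave the response to ATRA, a known inducer of neutrophil-like maturation in this line. PTGES, which encodes a prostaglandin E synthase, was at least 124-fold higher than vehicle at 6 h and at least 271-fold higher at 24 h. TGM2, a transglutaminase gene induced by retinoids, was 14.6-fold higher at 6 h and at least 34.9-fold higher at 24 h. CYP26A1, the enzyme that degrades retinoic acid, was 7.82-fold higher at 6 h and 8.18-fold higher at 24 h. CD36 was 30.4-fold higher at 24 h, the potassium channel subunit gene KCNE1 24.1-fold and the macrophage receptor gene VSIG4 16.1-fold. None of these passed the limma test, whose spread over 8 arrays also holds changes of the vibsanin A and PMA effects between the times. The time-averaged log2 difference had a 95% interval of 2.39 to 3.61 for CYP26A1 (limma adjusted p = 0.175). PTGES, with vehicle under the floor, had a limma adjusted p of 0.268.

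At 6 h KCNE1 was 9.15-fold higher, the immune receptor gene LILRA5 7.16-fold and MERTK, a receptor kinase of phagocytes, 6.49-fold, and ADH1C, ADH1A, SYT2 and SYN1 were at least 5.59-fold, 5.36-fold, 3.79-fold and 2.56-fold higher. ADH1A and ADH1C are near copies and may share probe signal. At 24 h MERTK was at least 11.3-fold higher, ADGRG3 at least 9.93-fold, the chemokine gene CCL24 at least 8.90-fold, the P-selectin gene SELP at least 4.68-fold and BPI at least 2.56-fold. Lower at 6 h were BCL11A (4.11-fold), WNT7B (3.46-fold), SLC1A3 (3.42-fold), FJX1 (3.35-fold), the carbonic anhydrase gene CA2 (3.11-fold), IRX3 (3.06-fold), DDN (3.02-fold) and S1PR3 (at least 2.29-fold), while RTL3 and S100A16 were under the floor on both arrays. Lower at 24 h were TCEA3 (10.3-fold), LDHD (9.34-fold), CA2 (7.40-fold), the potassium channel gene KCNN4 (6.76-fold), IL1RN (at least 5.99-fold), the telomerase gene TERT (at least 5.17-fold), WNT7B (at least 5.05-fold) and S1PR3 (at least 1.34-fold), and IL2RB and PLA2G7 were under the floor on both. LDHD rested on its vehicle array, with an intensity of 70.4 in vehicle at 6 h and 978 at 24 h.

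Retinoic acid response genes were the group with the largest median under ATRA. Of 17 measured, 7 were at least 2-fold higher and 1 lower at 6 h, and 8 higher and 0 lower at 24 h, with medians of 0.78 and 0.82, above all 10000 random lists. PLAAT4 was at least 5.11-fold higher at 24 h, the receptor gene RARB was higher by 1.40 at 6 h and ASB2 by 1.22 at 24 h, and CRABP2, a retinoic acid binding protein, was at −1.49 at 6 h. CRABP2 had vehicle intensities of 179.7 at 6 h and 70.9 at 24 h, so its 6 h difference may rest on the 6 h vehicle array. CD38, a surface enzyme, was 2.18-fold higher at 6 h and 1.70-fold at 24 h. With the other agents CD38 was lower at 24 h, with intensities of 5257 in vehicle, 959 with vibsanin A and 240 with PMA. By limma 0 of the 17 changed over all genes and 5 rose adjusted over the list alone. Under vibsanin A the same list had medians of −0.09 and 0.32, CYP26A1 was at least 1.32-fold lower at 6 h, and 1 member rose by limma (ASB2), against 1 that rose and 2 that fell adjusted over the list alone.

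Neutrophil genes had a median of 0.17 at 6 h and 0.46 at 24 h with ATRA, where 4 of 11 were at least 2-fold higher and 0 lower. ORM1, an acute phase protein gene that may share probe signal with ORM2, was higher by 2.42, S100A9 by 1.86 and CSF3R, the receptor for the granulocyte growth factor, by 1.35. Promyelocyte and progenitor genes had medians of −0.43 and −0.38, below all 10000 random lists, with 1 and 3 of 15 at least 2-fold lower. MYC was at −1.22 at 6 h, and MS4A3 and CTSG at −1.47 and −1.27 at 24 h. Monocyte and macrophage markers had medians of −0.01 and 0.08, with ITGAM higher by 0.82 and 1.60. In the NADPH oxidase list, NCF1 was higher by 1.46 and CYBB, its catalytic subunit gene, by 1.15 at 24 h, with a median of 0.18 after 0.03 at 6 h. CYBB intensities at 24 h were 7572 in vehicle, 16859 with ATRA, 13721.5 with vibsanin A and 9454 with PMA. Interferon response genes had medians of 0.51 and 0.42, above all random lists, with IFIT3 higher by 1.14 at 6 h and IFI6 by 1.28 at 24 h. By limma 0 genes of these 5 lists changed over all genes, and adjusted over the list alone 1 rose in the oxidase list and 1 in the interferon list.

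Cell cycle genes were near vehicle with ATRA. The median was −0.03 at both times for the 28 DNA replication genes and 0.11 and 0.02 for the 26 G2/M and mitosis genes, with 0 at least 2-fold different. Ribosome biogenesis genes had medians of −0.32 and −0.18, lysosome genes 0.15 and 0.32 with CTSD higher by 1.90 at 24 h, and sterol genes 0.06 and 0.32, beside 0.25 between the vehicle arrays. Immediate early genes had medians of 0.11 and 0.07, of which the first became −0.13 against the mean of both vehicle arrays, and NF-kB targets had 0.06 and 0.07. For adhesion genes the medians were 0.13 and 0.12, for CDK inhibitors 0.22 and 0.09, for apoptosis regulators 0.06 and 0.05 with BCL2 at −1.10 and −1.69, and for protein kinase C signalling −0.24 and −0.03. Heat shock genes had 0.09 and −0.03, NRF2 targets −0.05 and −0.02, unfolded protein response genes −0.08 and −0.22, MHC class II genes −0.03 and −0.11, lipid efflux genes 0.01 and 0.15 (0 at 24 h with dim intensities raised to 64) and housekeeping genes 0.02 and 0.01. Medians of the other cell types were 0.00 and −0.25 for lymphocyte, −0.32 and −0.26 for erythroid and megakaryocyte, and 0.09 and 0.13 for epithelial and stromal markers. Limma called 0 genes in each of these lists under ATRA, over all genes and adjusted over the list alone.

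ATRA gave 142 genes at least 2-fold higher and 84 lower at 6 h, and 189 higher and 94 lower at 24 h. At both times 85 were higher and 23 lower, where independent lists would share 2.78 and 0.817. Limma called 0 genes over all 8 arrays, with 427 at an unadjusted p under 0.05, and 0 with any array left out. With the 4 ATRA and vehicle arrays alone, where the spread holds no vibsanin A or PMA array, it called 108 higher and 38 lower, with 1536 unadjusted. That fit had 1 residual degree of freedom and prior degrees of freedom of 4.42, so each gene's spread rested mostly on the other genes.

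The last comparison set vibsanin A beside ATRA, an agent of another kind of maturation. Averaged over the times, CDKN1A was higher with vibsanin A by 5.23 on the log2 scale (95% interval 4.35 to 6.12, limma adjusted p = 0.0127), CCL4 by 7.03 (adjusted p = 0.0277), ICAM1 by 3.75 and NFKB2 by 3.24 (adjusted p = 0.0103 for both, by limma). CYP26A1, under the floor with vibsanin A, was lower (intensities of 29.8 with vibsanin A and 659 with ATRA at 6 h, limma adjusted p = 0.0103), and for PTGES the difference was −5.90 (limma adjusted p = 0.0432). The limma test called 262 genes higher and 101 lower with vibsanin A than with ATRA. All 363 called had the same sign at both times, which the fit favours. At an unadjusted p under 0.05 the limma test called 2280. Without either PMA array it called 51, and without any 1 of the vibsanin A, ATRA or vehicle arrays it called 0 (1013 to 2064 unadjusted).

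Some genes moved in opposite directions under these agents. At 24 h 26 genes were at least 2-fold higher with ATRA and lower with vibsanin A, of which 26 were also at least 2-fold lower with PMA, and 29 were lower with ATRA and higher with vibsanin A, of which 28 were higher with PMA. With intensities under 64 set to 64, these 26 and 29 genes became 21 and 14. Among the former, CSF3R was at 1.35 with ATRA and −1.59 with vibsanin A, and LILRA5 at 2.96 and −1.99. Among the latter, KCNN4 was at −2.76 with ATRA and 3.67 with vibsanin A, and VIM at −1.79 and 5.30. At 6 h the numbers were 7 and 17, of which 4 and 17 were also at least 2-fold different in the direction of vibsanin A with PMA, or 5 and 10 with intensities under 64 set to 64. What independent lists would share in opposite directions was not computed, so these counts are not shown to exceed it. At 24 h 189 genes were higher and 94 lower with ATRA, and 1239 higher and 1257 lower with vibsanin A, of 9667. Sharing with PMA was common among all genes that differed with vibsanin A, at 1100 of those 1239 and 1137 of those 1257. In the same direction, 75 higher and 45 lower genes were shared at 6 h, where independent lists would share 9.53 and 4.18, and 108 and 51 at 24 h, where they would share 24.2 and 12.2, and part of this excess may come from the shared vehicle array.

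The differences of vibsanin A and ATRA from vehicle correlated with r = 0.414 at 6 h and 0.281 at 24 h. A shared vehicle array gave 0.501 in simulated groups with no effect, which is not the value that sharing gives where an agent has effects. The covariances were 0.12 and 0.16, beside a simulated 0.04. Against different vehicle arrays r was 0.385 and 0.277 at 6 h and 0.128 and 0.242 at 24 h. PMA and ATRA gave r = 0.389 at 6 h and 0.25 at 24 h, with covariances of 0.14 and 0.15, and against different vehicle arrays 0.368 and 0.275 at 6 h and 0.106 and 0.214 at 24 h. Higher genes shared by PMA and ATRA numbered 75 and 98 (11.7 and 24.9 for independent lists), lower genes 46 and 49 (6.46 and 13.7), and genes in opposite directions 30 and 70, or 23 and 47 with intensities under 64 set to 64. These comparisons share a vehicle array too, and for the opposite directions no number for independent lists was computed.

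**Figure D4:**
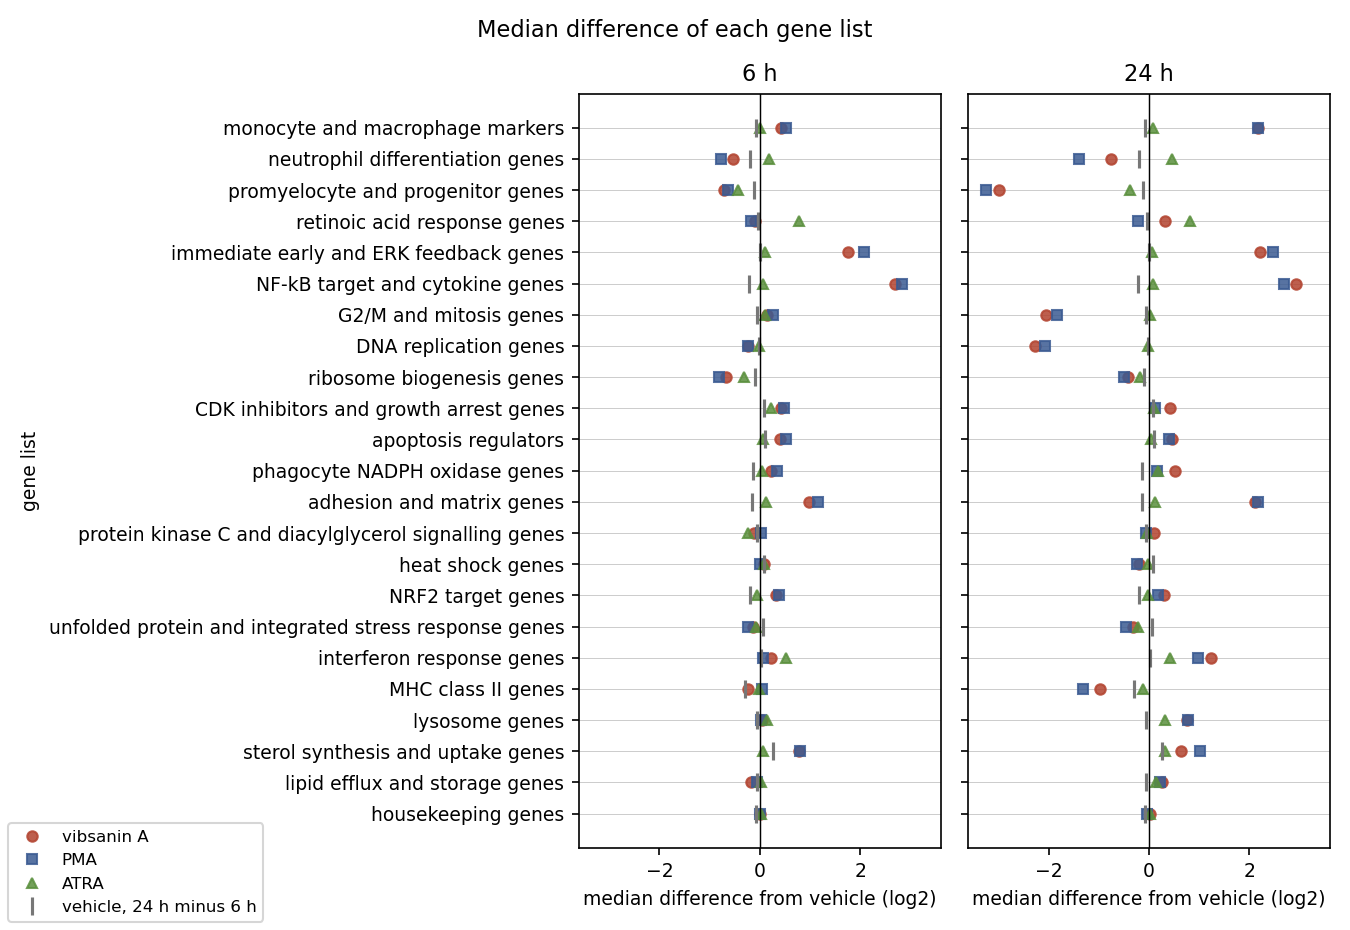
Median log2 difference from vehicle of each gene list with at least 5 measured members, at 6 h (left) and 24 h (right), with symbols for the agents and a grey bar for the 24 h against the 6 h vehicle array in both panels. At 24 h DNA replication genes lay at −2.26 with vibsanin A, −2.07 with PMA and −0.03 with ATRA.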

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

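The tests of whether the same RNA lay on both 6 h arrays or on both 24 h arrays of vibsanin A and PMA, with and without removal of trends, and the test with only 1 agent set against the 6 h vehicle array, were chosen only after the result was seen. Over all genes, 9 were at least 2-fold higher at 6 h and lower at 24 h with vibsanin A and 11 the reverse, 12 and 16 with PMA, and 2 and 0 with ATRA, or 8 and 8, 11 and 15, and 1 and 0 with intensities under 64 set to 64. Of the genes named by the rule fixed beforehand, CD14, CCL3L1 and S100A16 had differences from vehicle of opposite sign and at least 2-fold at 6 h and 24 h, with 1 array behind each value, and the differences between the times were not tested. CD14 was at −1.68 at 6 h and 4.26 at 24 h with vibsanin A, and at −1.72 and 1.05 with PMA. CCL3L1 was at 1.02 and −1.14 with ATRA, and its vehicle intensities were 332 at 6 h and 663 at 24 h. S100A16 was at −1.72 and 6.41 with vibsanin A, but both 6 h arrays and the 24 h vehicle array lay under the detection floor, so its 6 h value is of no weight and at 24 h it was at least 18.5-fold higher. Signal was also present in probes that carry no gene name here. Of 14121 such probes that were bright enough, 303 at 6 h and 1114 at 24 h were at least 4-fold different from vehicle with vibsanin A, 467 and 1300 with PMA and 19 and 48 with ATRA, while 10 were between the vehicle arrays.

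The first pattern weighed was the correlation of the vibsanin A and PMA differences. A shared vehicle array is argued against as its whole cause, since the lowest of the 4 correlations against different vehicle arrays was 0.900. The share of responding genes with the smaller difference under vibsanin A, 81.8% at 6 h and 59.6% at 24 h, and the correlation of 6 h and 24 h vibsanin A minus PMA differences, r = 0.292 across 2567 genes, do not alone exclude the same RNA on both arrays, since an array effect on the size of differences gives them too. After trends on response and level were removed, that correlation was 0.223 over genes that responded at 6 h and 0.181 over those at 24 h, where the same RNA with such an effect leaves noise that does not correlate, which argues against it, and array effects of other kinds were not tested. Alike responses to these agents, at the doses used, stay a hypothesis that may hold.

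The second pattern was the smaller size of the vibsanin A differences. A vibsanin A array with a compressed scale could give genes with little response a negative slope on the vehicle level. The steeper slope was −0.0209 over 4861 genes at 24 h, beside −0.0160 for PMA, and at 6 h it was −0.00928 over 6317 genes, beside −0.0124. These slopes cannot decide, because scaling to near-identical quantiles before deposit keeps them small whether or not an array was compressed. Scaling between arrays stays open too, because quantile normalization moved almost nothing on values that already had near-identical quantiles. After it, 59.3% at 24 h and 82.1% at 6 h of responding genes still had the smaller difference under vibsanin A. A lower effective dose of vibsanin A than of PMA is an open biological candidate explanation, and no dose series was analysed here.

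The third pattern was the correlation of the ATRA and vibsanin A differences at 6 h. A shared vehicle array as its whole cause is argued against by the correlations against different vehicle arrays, which were 0.277 and 0.385. A 6 h vehicle array that stands apart is argued against as the whole cause by the same 0.277, since only 1 agent was then set against it. The r of 0.477 over 7551 genes that differed by under 0.3 between the vehicle arrays was not used to decide, because both differences subtract the same array. The 0.501 of the simulation holds for groups with no effect, so it does not say what sharing gives among these genes. A response common to these agents may be part of the pattern and stays a hypothesis.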

How the results depend on the processing

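Intensities under 64 set to 64 and each row as its own feature were alternatives chosen only after seeing the data. Quantile normalization, centring on the median and the brightest row of each gene moved no count of genes by over 1.5 times. With no filter on dim genes, which tests more genes near the background, the counts of genes at least 2-fold higher and lower were 1030 and 947 for vibsanin A at 6 h, 349 and 259 for ATRA at 6 h, 463 and 367 for ATRA at 24 h and 320 and 325 between the vehicle arrays, and 1192 were lower with PMA at 6 h. The limma counts were then 291 for vibsanin A, 693 for PMA and 136 for vibsanin A against ATRA. Changes of sign were recorded only for list medians outside the central 95% of random lists. Those that changed sign with no filter, since more dim members entered, were −0.038 for monocyte and macrophage markers under PMA at 6 h and −0.12 and −0.41 for lymphocyte markers under vibsanin A at 6 h and 24 h. With the stricter filter, which tests fewer genes, the higher and lower counts were 325 and 161 for vibsanin A at 6 h and 616 and 551 at 24 h, 391 and 255 for PMA at 6 h and 641 and 603 at 24 h, 70 and 24 for ATRA at 6 h and 95 and 24 at 24 h, and 11 and 11 between the vehicle arrays. By limma it left 769 for PMA and 230 for vibsanin A against ATRA. With each row as its own feature, which counts more features, they were 1566 and 1127 for vibsanin A at 6 h and 2957 and 3074 at 24 h, 1922 and 1685 for PMA at 6 h and 3090 and 3392 at 24 h, 378 and 179 for ATRA at 6 h and 420 and 207 at 24 h, and 163 and 125 between the vehicle arrays. Against the mean of both vehicle arrays 55 genes were lower with ATRA at 6 h, and the immediate early median under ATRA at 6 h changed sign to −0.13 (the cause was not tested). Raised to the floor, 23 genes were lower at 24 h than at 6 h in vehicle, since dim differences vanish. With different vehicle arrays the correlation with ATRA at 24 h was 0.128 for vibsanin A and 0.106 for PMA with ATRA set against the 6 h vehicle array, and 0.242 and 0.214 with the vehicle arrays swapped (the cause was not tested). With only the 4 arrays of a contrast, which leave less to estimate the spread from, limma called 0 for vibsanin A and 0 for PMA (1613 and 1748 at an unadjusted p under 0.05) and 146 for ATRA, where the cause was not tested. Leaving out 1 array at a time, where a lone array is assumed to vary like the other groups, gave limma counts of 0 to 102 for vibsanin A, 0 to 498 for PMA, 0 to 51 for vibsanin A against ATRA, and 0 to 0 for ATRA and for vibsanin A against PMA. The count was 0 without the 6 h vehicle array or without the 24 h vehicle array for each of these contrasts, with 2247 and 1694 unadjusted for vibsanin A. Of the other values, 71 counts, 41 limma counts, 40 correlations, 799 list medians and 998 values of named genes stayed close. The 41 limma counts include those of ATRA and of vibsanin A against PMA that stayed at 0, which show no stability of calls. For the contrasts with calls, leaving out any array moved the limma count by over 1.5 times or to 0. A further 121 list medians and 77 values of named genes moved with no change of sign recorded. For genes such a change was recorded only where the difference was at least 2-fold, so smaller values may have changed sign. No paired analysis was possible because each group has 1 array and the labels link no arrays by culture, although differences were taken within a time and time was a term of the model. Signal over background limits the dim genes: between the vehicle arrays the standard deviation was 0.66 among the dimmest genes and 0.20 among the brightest.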

Other observations

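The gene families below were chosen after their values were seen, and the signs of their medians were the same after quantile normalization and after centring on the median. All 16 measured H2B histone genes were at least 2-fold higher than vehicle at 24 h with vibsanin A, from 1.25 to 1.85 on the log2 scale with a median of 1.65, and all 16 were with PMA, with a median of 1.53. Their median was −0.05 with vibsanin A and 0.31 with PMA at 6 h, and −0.09 with ATRA at 24 h. Between the vehicle arrays the median was 0.18 for H2B, 1.33 for 11 H4 genes, of which 7 were at least 2-fold higher at 24 h, and 0.86 for 11 H3 genes. At 24 h the H3 median was −0.33 with vibsanin A and −0.41 with PMA, and the H4 median was 0.23 and 0.36, where 2 were at least 2-fold higher and 3 lower with vibsanin A, and 1 and 3 with PMA. Near-identical histone copies share sequence, so these are not 16 separate observations.

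Of 12 measured CC chemokine genes, 10 were at least 2-fold higher with vibsanin A at 6 h, with a median of 5.18, beside 5.31 with PMA and 0.55 with ATRA. With intensities under 64 set to 64, these medians were 4.28, 5.10 and 0.55, and 10 were still at least 2-fold higher with vibsanin A. A chemokine or integrin gene dim in vehicle passes the filter only through an agent array where it is bright. At 6 h CCL1, for example, had intensities of 31.1 in vehicle and 3098 with vibsanin A. Raising intensities to 64 does not undo that, so part of the counts and medians of these families may come from the filter. The 6 integrin beta genes had medians of 3.48 with vibsanin A and 4.17 with PMA at 24 h, which the floor of 64 reduced to 2.05 and 2.12, and the 12 integrin alpha genes of 2.23 and 2.33, or 2.23 and 2.28 with the floor. Of 21 kinesin genes, 11 were at least 2-fold lower with vibsanin A and 13 with PMA at 24 h.

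Between the vehicle arrays, LDHD had an intensity of 70.4 at 6 h and 978 at 24 h, and FOS 902 and 2752, while EMP1 had 439.5 and 93.1 and HMOX1 1510.2 and 220.1.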
